A study of Homo sapiens with 18 samples.

How the data were processed

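Gene expression was measured in mesenchymal stromal cells, adherent cells that can form bone, fat and cartilage cells in culture. UCB1 and UCB2 are 2 cell populations grown from umbilical cord blood, and BM is an adult bone marrow population grown under the same conditions and to the same confluence, per the labels. Each of the 3 groups had 3 cultures, given as biological replicates per the labels. RNA of each of the 9 cultures was hybridised to an Affymetrix HG-U133A array and to an HG-U133B array, which gave 18 arrays. HG-U133A held 22283 probe sets and HG-U133B 22645. A probe set is a group of short oligonucleotides that reads 1 transcript.

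The deposited values are 1 number per probe set and array. Per the submitters' processing notes they come from RMA, robust multi-array average, which corrects background, normalizes arrays against each other and summarises the probes of a probe set. No RMA version is given in the sources used here. The deposited values were taken to be on the log2 scale because of their range: the highest values of HG-U133A arrays lay between 13.05 and 13.24. RMA compresses differences of dim probe sets toward 0. Whether the arrays of both types were normalized in 1 run is not given in the sources used here, so the 2 tables were never merged for a test of single probe sets.

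Array precision was judged from controls, since arrays give no read depth. The 27 poly-A control probe sets per array, for bacterial transcripts, were taken as unspiked because their median lay near the low end of each array. Their medians were 2.57 on HG-U133A and 3.93 on HG-U133B. Their highest means over the arrays, 5.04 and 5.48, served as the bound of their range. The medians of whole arrays were 5.22 to 5.30 on HG-U133A and 4.87 to 4.97 on HG-U133B. The bound thus lay near the array median on HG-U133A and above it on HG-U133B. A group mean under that bound cannot be told from background by this measure, so a fold change against it says little about the level of the lower group. The 18 spiked controls, the 3-prime minus 5-prime difference of GAPDH and ACTB and the 18S rRNA control were read per array as measures of hybridisation and RNA quality. The number of arrays limits the precision of every value.

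Probe sets were named from the platform annotation supplied with the values, with symbols looked up through gene identifiers in a RefSeq table of the assembly GRCh38.p14, used for names only. On HG-U133A, 19065 tested probe sets had 1 gene symbol, 1043 had several and 2107 had none. On HG-U133B these were 15426, 554 and 6597. Probe sets with several symbols or none stayed in the tests and were not named. Of the 34491 with 1 symbol, the gene identifier of 34454 was found in the RefSeq table. The 68 control probe sets of each array were left out of the tests, which left 22215 and 22577. No column of per-sample values was left unused.

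Differences between groups were tested with limma 3.58.1 in R 4.3.3, separately for each array type, with a linear model of the 3 group means over all 9 arrays, moderated variances (eBayes) and Benjamini-Hochberg adjustment over the probe sets of the array type. A difference was called at an adjusted p under 0.05. The 3 comparisons were UCB1 against UCB2, UCB1 against BM and UCB2 against BM, and an F test asked for any difference among the 3 groups. Values are given as log2 differences with the standard error of the model (SE), or as group means with the standard deviation (SD) over 3 cultures. Adjusted p values below come from this limma test unless a set test is named. Because every group is 1 cell population, the p values measure the spread between cultures, and a difference between groups cannot be told apart from a difference between donors.

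1 probe set stood for each gene. Probe sets whose names end in _x_at came last, HG-U133A came before HG-U133B, and then the highest mean over the 9 arrays decided. This gave 11783 genes on HG-U133A and 5694 on HG-U133B. The named genes follow a rule set before the data were examined. It took the 10 genes with the largest log2 difference in each direction among called genes whose groups did not overlap, and from each of 25 gene lists up to 4 members in each direction by the same criteria. Groups of 3 and 3 do not overlap by chance in 10% of genes. The rule gave 454 pairs of gene and comparison, and 218 of them were chosen for the text. That choice was made after the values were seen, and it preferred genes whose other probe sets had the same direction and whose call held without any 1 culture. The outcome for all 454 is given with the processing alternatives. Genes that reveal sex were left out of every list of named genes.

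The 25 gene lists were also set before the data were examined. They cover HOX genes, other patterning factors, WNT, Notch, TGF-beta and BMP, FGF and hedgehog signalling, proliferation, growth arrest, osteogenic, adipogenic, chondrogenic, neural, smooth muscle, stromal surface, extracellular matrix, imprinted and fetal growth, pluripotency, haematopoietic, endothelial, epithelial, interferon, inflammatory and haematopoietic support, sterol synthesis, and hypoxia and glycolysis genes. For each list the members higher, lower and not past the test are counted over both array types, and again with the adjustment over the list alone. On HG-U133B were 13 of 38 Notch genes, 16 of 81 other patterning factors and 6 of 15 hedgehog genes. There 121 probe sets were called for UCB1 against UCB2, and 812 without UCB1 replicate 2. A member read there that did not pass is therefore weak evidence of no difference. A competitive set test, limma's camera, compared each list with all other genes of HG-U133A, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 25 lists. It was repeated with the correlation estimated from the residuals. Lists share members, for example IL6 and IL1B in the growth arrest and inflammatory lists.

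Alternatives chosen before the data were examined were the replicate number as a block, leaving out dim probe sets, quantile normalization, centring each array on its median, a trended and robust variance prior, adjustment over both array types together, a 2-fold limit, a threshold of 0.01 for the F test, 1 probe set per gene, only the 2 groups compared, leaving out each culture in turn, and the other probe sets of each named gene. Array weights, and leaving out UCB1 replicate 2 and UCB2 replicate 2 together, were added after seeing the data. The fit was tested on simulated data with the spread of the real arrays and no other differences. For UCB1 against UCB2 over 22215 probe sets of HG-U133A it called 82% of changes of 1 and 100% of changes of 2 on the log2 scale. On the 22577 of HG-U133B it called 61% and 84%. In the simulated set test over 11935 genes the list raised for that comparison was found, and 0 of 72 tests of other lists were called. This says little about lists whose genes move together. Figures were drawn with matplotlib 3.10.9.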

Results

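The study asked which developmental genes distinguish 2 mesenchymal stromal cell populations from umbilical cord blood, UCB1 and UCB2, and set adult bone marrow stromal cells (BM) beside them. Messenger RNA levels of 3 cultures per group were read on 2 array types, HG-U133A and HG-U133B. On HG-U133A without UCB1 replicate 2, arrays of the same group correlated at Pearson r from 0.984 to 0.996 across probe sets. Arrays of different groups correlated there at r from 0.950 to 0.965. The HG-U133A array of UCB1 replicate 2 correlated with its own group at r from 0.988 to 0.991. On HG-U133B the corresponding ranges without UCB1 replicate 2 were 0.981 to 0.994 and 0.949 to 0.967. The HG-U133B array of UCB1 replicate 2 correlated with the other 8 arrays at r from 0.639 to 0.710, and its spiked controls had a mean of 6.54 against 8.52 to 8.87 on the others. The 18S rRNA control of BM replicate 1 read 8.95 on HG-U133A and 9.21 on HG-U133B, above all other arrays.

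**Figure D1:**
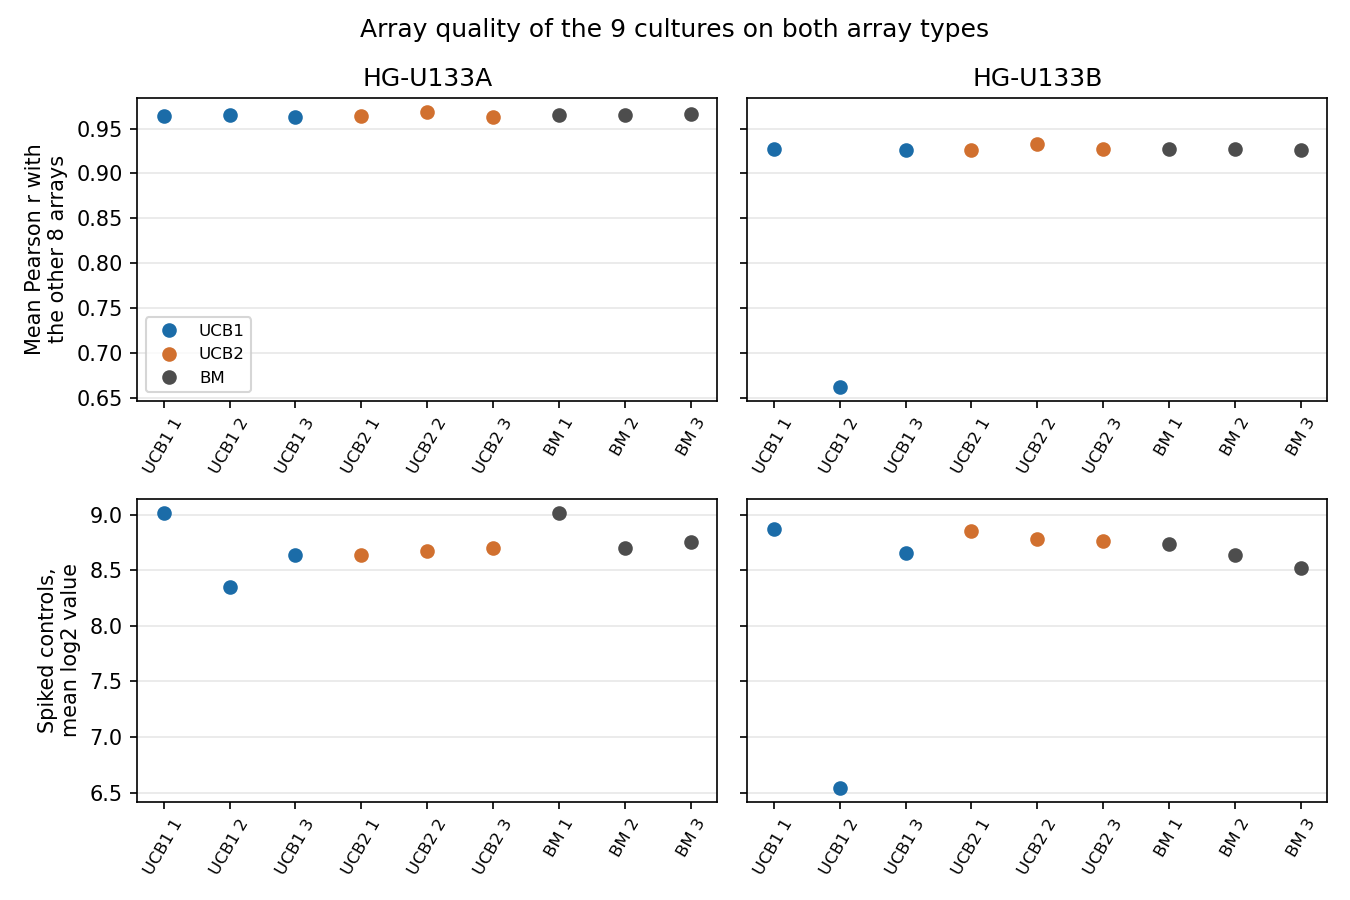
Mean Pearson correlation of each array with the other 8 arrays of its type (top, no unit) and mean log2 value of the spiked controls (bottom) for the 9 cultures on HG-U133A (left) and HG-U133B (right), 1 point per array. The HG-U133B array of UCB1 replicate 2 lies apart from the others, with a mean correlation of 0.662 and spiked controls at 6.54.

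The comparison of UCB1 with UCB2 addressed the main question of the study. UCB1 cultures had far higher levels of DCN, which encodes the matrix proteoglycan decorin (49.9-fold, mean 10.72 ± 0.47 against 5.08 ± 0.18 on the log2 scale, SD, n = 3 each). They also had higher CXCL12, a chemokine that retains blood progenitors in the marrow (43.6-fold, 8.57 ± 0.70 against 3.12 ± 0.30), and SFRP1, a secreted WNT antagonist (35.5-fold, 9.97 ± 0.10 against 4.82 ± 0.13). In the other direction, UCB2 cultures had higher SRGN, the granule proteoglycan serglycin (74.7-fold, 10.64 ± 0.02 against 4.42 ± 0.65), CCND2, a cyclin of the G1 phase (35.1-fold, 10.03 ± 0.78 against 4.89 ± 0.39), and the cytokine gene IL1B (27.2-fold, 10.43 ± 0.35 against 5.67 ± 0.09). The adjusted p values were 4.17e-08 for DCN, 8.77e-07 for CXCL12, 5.36e-09 for SFRP1, 1.04e-07 for SRGN, 2.66e-06 for CCND2 and 2.95e-08 for IL1B (limma, Benjamini-Hochberg).

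The remaining genes with the largest differences toward UCB1 included S100A4, a calcium-binding protein (log2 difference 5.28), SERPINF1, which encodes an antiangiogenic serpin (5.08), and TNFRSF11B, the decoy receptor osteoprotegerin (5.05). SULF1, a heparan sulfate sulfatase (4.97), the matrix genes FBLN1 (4.74) and MXRA5 (4.74), and FOXF1, a forkhead factor of visceral mesoderm (4.48), followed. Toward UCB2 these were HAPLN1, which links cartilage proteoglycan to hyaluronan (-5.02), BAMBI, a decoy receptor of BMP and TGF-beta (-4.82), and CYP1B1, a xenobiotic-metabolising enzyme (-4.65). MEST, an imprinted gene (-4.49), POSTN, the matrix protein periostin (-4.31), IL6 (-4.31) and the Notch ligand gene DNER (-4.30) completed the list. Adjusted p values of these genes ranged up to 5.7e-04, the value of DNER, which was read on HG-U133B. The fold toward UCB2 of POSTN was 11.9 without UCB1 replicate 2 instead of 19.8, and that of IL6 was 13.1 without UCB2 replicate 2 instead of 19.8. In 15 of the 20 genes named so far the mean of the lower group lay within the range of the unspiked controls. This limits their folds, and CXCL12, SFRP1, SRGN and CCND2 were among them.

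Genes that set position and regional identity in the embryo differed in both directions. Of 27 measured HOX genes, 6 were higher and 1 lower in UCB1, and 20 did not pass (7 and 1 passed when adjusted over the list alone; set test adjusted p = 0.214). HOXC10 was higher in UCB1 by 3.75 ± 0.22 (SE), HOXD11 by 1.55 ± 0.13, HOXC6 was 2.84-fold higher, and HOXB2 was lower by -1.07 ± 0.12. Of 81 other patterning factors, 16 were higher and 9 lower in UCB1 and 56 did not pass (18 and 10 adjusted over the list alone; set test adjusted p = 0.214). Without UCB1 replicate 2 and UCB2 replicate 2 together, 20 were higher and 11 lower. MEIS1, a HOX cofactor (3.64), TBX3, a limb and heart T-box factor (3.25), and SALL1, a zinc finger factor of kidney and limb (2.79), were higher in UCB1, and ZIC1, a neural and somite factor (-3.35), and FOXD1 (-2.25) were higher in UCB2. Both ZIC1 probe sets on HG-U133B had small values of opposite sign.

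**Figure D2:**
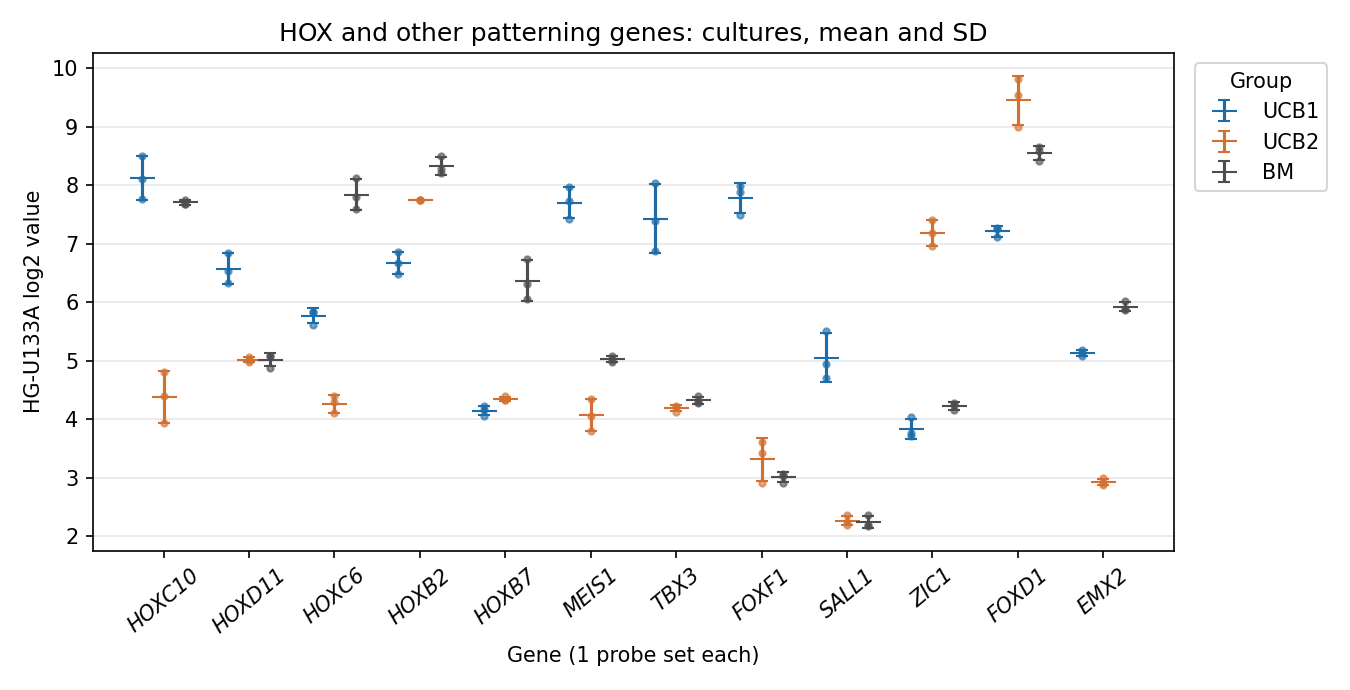
Log2 values on HG-U133A of 5 HOX genes and 7 other patterning factors in the 3 cultures of UCB1, UCB2 and BM, with small points for cultures, dashes for group means and bars for the SD. HOXC10 was 8.13 in UCB1, 7.71 in BM and 4.38 in UCB2, and FOXF1 was 7.79 in UCB1 and 3.31 in UCB2.

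Of 53 WNT pathway genes, 11 were higher and 3 lower in UCB1 and 39 did not pass (11 and 4 adjusted over the list alone; set test adjusted p = 0.214). Beside SFRP1, the ligand WNT2 (2.65) and the receptor FZD7 (2.14) were higher, and the receptor FZD6 was lower (-1.04). Of 59 TGF-beta and BMP genes, 8 were higher and 12 lower and 39 did not pass (11 and 15 adjusted over the list alone; set test adjusted p = 0.214). The ligand TGFB2 (-3.73) and INHBA, a subunit of activin A (-2.97), were lower in UCB1, and the BMP target ID1 was higher (5.22-fold, and 8.16-fold without UCB2 replicate 2). Of 38 Notch genes 3 were higher, 3 lower and 32 did not pass, with the same counts over the list alone (set test adjusted p = 0.912). Without UCB1 replicate 2 and UCB2 replicate 2 together, 1 was higher and 4 were lower. NOTCH2 (-0.76) and the protease gene ADAM17 (-0.81) were lower. Of 35 FGF genes 1, FGF13, was higher (2.78), 2 were lower, among them FGF1 (-1.02), and 32 did not pass, with the same counts over the list alone (set test adjusted p = 0.912). Of 15 hedgehog genes 2 were higher, 1 was lower and 12 did not pass, again with the same counts over the list alone (set test adjusted p = 0.369). The lower 1 was HHIP, a hedgehog-binding inhibitor (-1.85), read on HG-U133B. Its adjusted p of 0.00931 became 0.0862 when only UCB1 and UCB2 arrays were fitted and ranged from 0.00355 to 0.0862 over the alternatives.

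Genes of the dividing cell separated UCB1 from both other groups. Of 55 proliferation genes, 50 were higher in UCB1 than in UCB2, 0 were lower and 5 did not pass (50 and 0 adjusted over the list alone, median log2 difference 1.99; set test adjusted p = 1.08e-29, 3.64e-50 to 1.49e-20 over the other alternatives, and adjusted p = 0.366 with an estimated correlation), which was 0.716 in this list. The mitotic gene DLGAP5 was 13.1-fold higher, TOP2A, the topoisomerase of dividing cells, 10.1-fold and CDC20, an activator of the anaphase-promoting complex, 10.8-fold. RRM2, a subunit of ribonucleotide reductase, was 11.5-fold higher. The mean over the list was 7.09, 7.04 and 7.05 in the 3 UCB1 cultures and 4.77, 5.99 and 4.72 in UCB2 replicates 1, 2 and 3. Without UCB2 replicate 2 the folds were 23.2 for DLGAP5, 18.9 for TOP2A, 18.5 for CDC20 and 24.8 for RRM2, and without UCB2 replicate 1 they were 8.66 for DLGAP5 and 7.44 for RRM2.

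**Figure D3:**
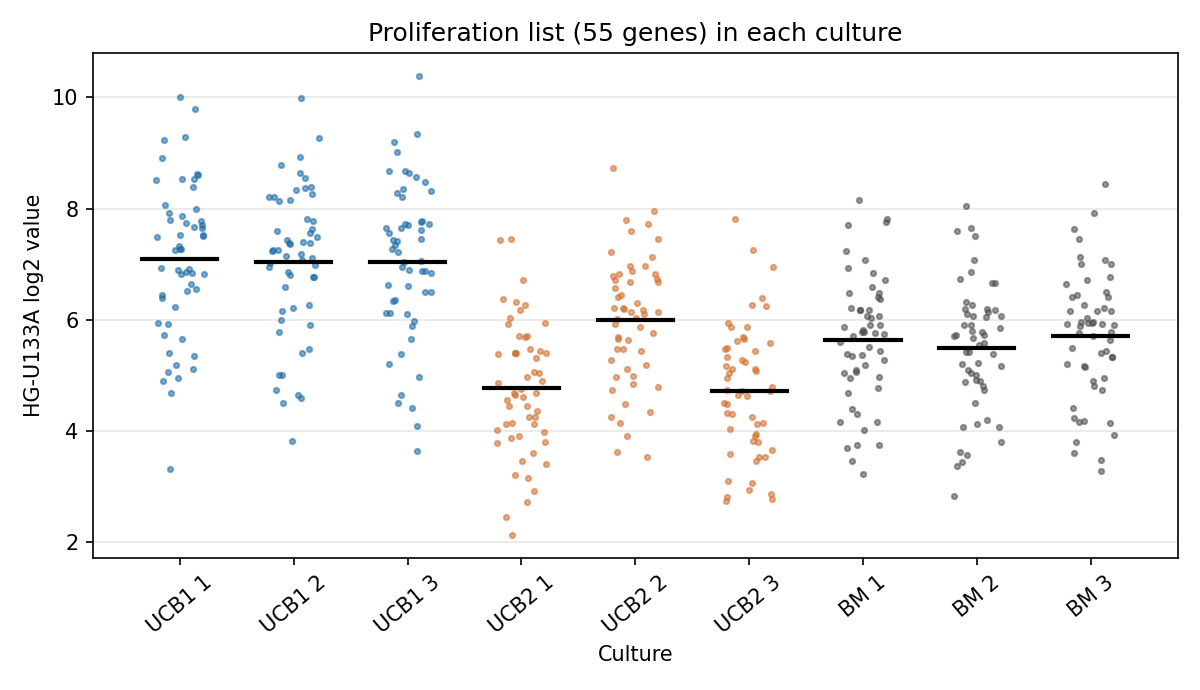
Log2 values on HG-U133A of the 55 genes of the proliferation list in each of the 9 cultures, 1 point per gene, with the mean of the list as a black line. The mean was 7.04 to 7.09 in UCB1 cultures, 5.50 to 5.71 in BM cultures, and 5.99 in UCB2 replicate 2 against 4.77 and 4.72 in the other UCB2 cultures.

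Some growth arrest genes differed in both directions, and most hypoxia and glycolysis genes were lower in UCB1. Of 31 growth arrest and senescence-associated genes, 7 were higher and 7 lower in UCB1 and 17 did not pass (8 and 8 adjusted over the list alone; set test adjusted p = 0.912), and the 7 lower were 4 without UCB1 replicate 2 or without UCB1 replicate 3. IGFBP5, an insulin-like growth factor binding protein, was higher (4.13), and IGFBP7 of the same family (-3.20) and CDKN2A were lower. CDKN2A, whose products arrest the cell cycle, was 6.72-fold higher in UCB2, and 10.9-fold without UCB2 replicate 2. Of 34 hypoxia and glycolysis genes, 22 were lower in UCB1 and 2 higher and 10 did not pass (26 and 2 adjusted over the list alone; set test adjusted p = 1.13e-11, 5.46e-14 to 3.9e-10 over the other alternatives, and adjusted p = 0.366 with an estimated correlation). ANGPTL4, a lipase inhibitor induced by low oxygen (-3.29), VEGFA, an angiogenic factor (-1.73), and the factor BHLHE40 (-1.74) were lower. The vasodilator peptide gene ADM was higher (3.70-fold, adjusted p = 0.0144), with 2.44-fold without UCB2 replicate 2 and an adjusted p of 0.0614 when only the 6 cord blood arrays were fitted, the highest of 6.66e-04 to 0.0614 over the alternatives. Of 37 interferon and antigen presentation genes, 11 were higher, 1 was lower and 25 did not pass, with the same counts over the list alone (set test adjusted p = 0.00237, 7.10e-04 to 0.0110 over the other alternatives, and adjusted p = 0.366 with an estimated correlation). PSMB9, an immunoproteasome subunit (2.29), and GBP2, an interferon-induced GTPase (1.96), were higher, and RIGI, a sensor of viral RNA, was lower (-1.12).

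Lists of differentiation and stromal genes did not pass the set test. Of 25 osteogenic genes 2 were higher in UCB1, 5 were lower and 18 did not pass, with the same counts over the list alone (adjusted p = 0.245). BMP4 was higher (0.89), and VDR, the vitamin D receptor, was lower (-1.95). Of 30 adipogenic genes 7 were higher, 0 were lower and 23 did not pass (8 and 2 adjusted over the list alone; adjusted p = 0.214), among them CEBPD (2.19) and PPARG (1.19), both transcription factors of fat cell formation. Of 27 chondrogenic genes 2 were higher, 2 were lower and 23 did not pass, with the same counts over the list alone (adjusted p = 0.912). The cartilage factor SOX9 was lower (-0.99) and the matrix gene FMOD higher (0.65). Of 39 neural genes 5 were higher, 3 lower and 31 did not pass (8 and 4 adjusted over the list alone; adjusted p = 0.912), and the 5 higher were 3 without UCB2 replicate 3. NES, the intermediate filament of neural progenitors, was higher (2.85), and the neurofilament NEFM was lower (-3.66). Of 29 smooth muscle genes 4 were higher, 5 lower and 20 did not pass (4 and 6 adjusted over the list alone; adjusted p = 0.917), with higher ACTA2, smooth muscle actin (3.43), MYLK (3.26) and ACTG2 (3.13), and lower CNN1, calponin (-1.23).

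Of 36 stromal surface markers 9 were higher, 7 lower and 20 did not pass (11 and 11 adjusted over the list alone; adjusted p = 0.823). The growth factor receptors PDGFRA (2.75) and PDGFRB (2.15) and the stromal antigen CD248 (3.32) were higher in UCB1, and the adhesion molecule ICAM1 was lower (-1.43). Of 59 extracellular matrix genes 21 were higher, 16 lower and 22 did not pass (24 and 19 adjusted over the list alone; adjusted p = 0.214), with higher FBN2 (3.46) and COL14A1 (3.42) and lower VCAN (-1.95) and THBS1 (-1.85). Of 26 imprinted and fetal growth genes 5 were higher, 4 lower and 17 did not pass (5 and 5 adjusted over the list alone; adjusted p = 0.917), with HMGA1, a chromatin protein of fetal cells, higher (1.26). The 5 higher were 3 without UCB1 replicate 3. Of 17 pluripotency genes 1, KLF4, was higher (1.61), 0 were lower and 16 did not pass, with the same counts over the list alone (adjusted p = 0.823). Of 38 inflammatory and haematopoietic support factors 6 were higher, 10 lower and 22 did not pass (8 and 11 adjusted over the list alone; adjusted p = 0.217), with the growth factor HGF higher (1.40) and the chemokine CCL20 lower (-2.34). Of 19 sterol synthesis genes 1 was higher, 0 were lower and 18 did not pass, and 0 and 0 passed when adjusted over the list alone (adjusted p = 0.245). This list passed as lower in UCB1 without UCB2 replicate 2 (adjusted p = 0.0233) or without the 2 cultures that stood apart (0.0393), with a range of 0.0233 to 0.916 over its alternatives.

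Markers of other cell types were compared in the same way. Of 34 haematopoietic and erythroid genes 1, the invariant chain CD74, was higher in UCB1 (0.68), 1, SRGN, was lower and 32 did not pass, with the same counts over the list alone (adjusted p = 0.427). Of 27 endothelial genes 1 was higher, 1 was lower and 25 did not pass, with the same counts over the list alone (adjusted p = 0.250). Of 27 epithelial genes 3 were higher, 4 lower and 20 did not pass (3 and 5 adjusted over the list alone; adjusted p = 0.504), with the junction genes CLDN11 higher (1.66) and DSP lower (-1.77). The sign of the median, the mean and the set test of a list was not the same in this comparison for other patterning factors, Notch, FGF, hedgehog, growth arrest, smooth muscle, stromal surface, imprinted and pluripotency genes.

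Over HG-U133A 3053 of 22215 probe sets differed between UCB1 and UCB2, 1757 higher and 1296 lower in UCB1, and 1019 of them differed at least 2-fold. Over HG-U133B 121 of 22577 differed, 17 higher and 104 lower. With the replicate number as a block 66 differed, 6 higher and 60 lower. When only UCB1 and UCB2 arrays were fitted 19 differed. On HG-U133B 812 differed without UCB1 replicate 2, 425 higher and 387 lower. Higher and lower counts were 18 and 195 without UCB2 replicate 2, 8 and 66 without UCB1 replicate 1, 25 and 96 without UCB1 replicate 3, 6 and 54 without UCB2 replicate 1, and 7 and 53 without UCB2 replicate 3. Without BM replicates 1, 2 and 3, which share the estimate of the spread, they were 7 and 59, 6 and 58, and 7 and 63. Of list members called lower in UCB1, HG-U133A held 7 of 9 other patterning, 2 of 3 Notch, 6 of 7 stromal surface and 21 of 22 hypoxia genes. The rest of these, like HHIP, were read on HG-U133B. The lower group also lay within the range of the unspiked controls, which limits the fold, for 22 genes named from lists: HOXC10, HOXD11, HOXC6, MEIS1, TBX3, ZIC1, WNT2, TGFB2, FGF13, HHIP, DLGAP5, CDC20, TOP2A, VDR, PPARG, NEFM, COL14A1, PSMB9, GBP2, RIGI, CCL20 and SALL1.

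Cord blood population UCB1 was then set against adult marrow cells. MMP1, interstitial collagenase, was 181-fold higher in UCB1 than in BM (10.25 ± 0.62 against 2.75 ± 0.06 on the log2 scale, SD, n = 3 each), SFRP1 34.4-fold (9.97 ± 0.10 against 4.87 ± 0.16) and FOXF1 27.6-fold (7.79 ± 0.26 against 3.00 ± 0.09). Lower in UCB1 were FLG, the epidermal protein filaggrin (136-fold higher in BM, 2.39 ± 0.10 against 9.48 ± 0.05), SRGN (129-fold, 4.42 ± 0.65 against 11.43 ± 0.11) and MFAP5, a microfibril protein (113-fold, 4.36 ± 0.15 against 11.17 ± 0.10). The adjusted p values were 3.44e-08 for MMP1, 2.95e-09 for SFRP1, 4.64e-08 for FOXF1, 2.52e-11 for FLG, 3.19e-08 for SRGN and 2.31e-08 for MFAP5 (limma).

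Other genes with the largest differences toward UCB1 were CTSC, a lysosomal protease (4.75), GREM1, a BMP antagonist (4.63), TRHDE, a peptidase (4.48), and ERAP2, a peptidase that trims antigenic peptides (4.42). ACTG2, a smooth muscle actin (4.28), HMGA2, a chromatin protein of embryonic tissue (4.17), and LRRC17 (4.07) followed. Toward BM these were IGFBP2 (-5.70), CYP1B1 (-5.41), LUM, the matrix proteoglycan lumican (-5.39), ANKRD37 (-5.37), HAPLN1 (-5.33), FNDC1 (-5.23) and ISLR (-4.76). Adjusted p values of these genes ranged up to 3.01e-05, the value of IGFBP2. In 18 of these 20 genes the mean of the lower group lay within the range of the unspiked controls. This limits their folds, and MMP1, SFRP1, FOXF1, FLG, SRGN and MFAP5 were among them.

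Of 27 HOX genes 2 were higher in UCB1 than in BM, 9 lower and 16 did not pass (3 and 10 adjusted over the list alone; set test adjusted p = 0.0357, 0.0131 to 0.0762 over the other alternatives, and adjusted p = 0.342 with an estimated correlation). This adjusted p was 0.0506 without UCB1 replicate 1, 0.0642 without UCB1 replicate 2, 0.0560 without dim genes, 0.0762 without the 2 cultures that stood apart and 0.0706 with quantile normalization. HOXD11 was higher (1.56 ± 0.13, SE), and HOXB7 (-2.23 ± 0.15) and HOXC6 (-2.07 ± 0.14) were lower. Of 81 other patterning factors 15 were higher, 14 lower and 52 did not pass (16 and 15 adjusted over the list alone; set test adjusted p = 0.750), with TBX3 (3.11) and MEIS1 (2.68) higher and IRX3, a homeobox factor, lower (-2.07). Without UCB1 replicate 2 and UCB2 replicate 2 together, 20 of these factors were higher and 15 lower. Of 53 WNT genes 9 were higher, 9 lower and 35 did not pass (9 and 10 adjusted over the list alone; adjusted p = 0.829), with WNT2 higher (2.46) and the WNT antagonist SFRP4 lower (-3.29). Of 38 Notch genes 3 were higher, 3 lower, among them NOTCH2 (-0.77), and 32 did not pass, with the same counts over the list alone (adjusted p = 0.750). Without UCB1 replicate 2 and UCB2 replicate 2 together, 4 Notch genes were higher and 2 lower. Of 35 FGF genes 5 were higher, 4 lower and 26 did not pass, with the same counts over the list alone (adjusted p = 0.815). FGF13 was higher (2.90) and FGF7, a growth factor for epithelia, lower (-2.74). Of 15 hedgehog genes 1 was higher, 1 lower and 13 did not pass, with the same counts over the list alone (adjusted p = 0.197).

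Of 59 TGF-beta and BMP genes 10 were higher, 18 lower and 31 did not pass (13 and 19 adjusted over the list alone; set test adjusted p = 0.0374, 0.0189 to 0.0706 over the other alternatives, and adjusted p = 0.236 with an estimated correlation). The value was 0.0596 without UCB1 replicate 3, 0.0575 without the 2 cultures that stood apart and 0.0706 with quantile normalization. The growth factor GDF5 was higher (1.52), and BAMBI (-4.56) and LTBP2, which is related to TGF-beta binding proteins (-3.27), were lower.

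Of 55 proliferation genes 47 were higher in UCB1 than in BM, 0 were lower and 8 did not pass (49 and 0 adjusted over the list alone, median log2 difference 1.57; set test adjusted p = 4.07e-15, 2.06e-27 to 3.19e-09 over the other alternatives, and adjusted p = 0.300 with an estimated correlation). DLGAP5 (2.63), CDC20 (2.61) and the mitotic kinase gene NEK2 (2.42) were higher. Of 31 growth arrest genes 3 were higher, 10 lower and 18 did not pass (5 and 11 adjusted over the list alone; adjusted p = 0.198, and 0.0251 as lower with dim genes left out, range 0.0251 to 0.275 over its alternatives), with IGFBP5 higher (2.14) and IGFBP3 lower (-3.92). Of 34 hypoxia and glycolysis genes 0 were higher, 20 lower and 14 did not pass (0 and 22 adjusted over the list alone; set test adjusted p = 9.38e-11, 1.22e-13 to 1.14e-09 over the other alternatives, and adjusted p = 0.236 with an estimated correlation). ANGPTL4 (-3.18) and the glucose transporter SLC2A1 (-2.23) were lower, as was ANKRD37. The mean of the list was 8.05 ± 0.13 in UCB1, 8.73 ± 0.13 in UCB2 and 8.92 ± 0.01 in BM (SD, n = 3).

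Of 37 interferon and antigen presentation genes 13 were higher in UCB1 than in BM, 3 lower and 21 did not pass (14 and 3 adjusted over the list alone; set test adjusted p = 0.0480, 0.00370 to 0.0936 over the other alternatives, and adjusted p = 0.300 with an estimated correlation). This adjusted p was 0.0936 without UCB1 replicate 1, 0.0722 without UCB1 replicate 3, 0.0518 without UCB2 replicate 3 and 0.0790 without BM replicate 3. PSMB9 was higher (1.62), and BST2, an antiviral tether, lower (-0.92). Of 38 inflammatory and support factors 6 were higher, 8 lower and 24 did not pass (8 and 8 adjusted over the list alone; adjusted p = 0.750), with HGF higher (1.07) and PTGES, a prostaglandin E synthase, lower (-2.55). Of 19 sterol synthesis genes 2 were higher, among them ACAT2 (0.49), 2 lower, among them INSIG1 (-0.93), and 15 did not pass, with the same counts over the list alone (adjusted p = 0.815).

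Lists of differentiation genes had members in both directions. Of 25 osteogenic genes 1, BMP4, was higher (0.70), 8 were lower and 16 did not pass (1 and 10 adjusted over the list alone; set test adjusted p = 0.0144, 0.00277 to 0.0454 over the other alternatives, and adjusted p = 0.300 with an estimated correlation), and the 8 lower were 5 without BM replicate 3. The cadherin CDH11 (-1.70) and the homeobox factor DLX5 (-1.12) were lower. Of 27 chondrogenic genes 2 were higher, 5 lower and 20 did not pass (2 and 6 adjusted over the list alone; set test adjusted p = 0.0357, 0.0144 to 0.0761 over the other alternatives, and adjusted p = 0.300 with an estimated correlation). The value was 0.0642 without UCB1 replicate 2, 0.0728 without the 2 cultures that stood apart and 0.0761 with quantile normalization. The cartilage matrix gene COMP was lower (-4.45) beside HAPLN1, and SOX9 was higher (0.59). Of 29 smooth muscle genes 4 were higher, 11 lower and 14 did not pass (4 and 13 adjusted over the list alone; set test adjusted p = 0.0144, 0.00346 to 0.0319 over the other alternatives, and adjusted p = 0.300 with an estimated correlation), and the 11 lower were 7 without BM replicate 3. The actin-binding gene SYNPO2 was lower (-3.99), and ACTG2 was higher. Of 30 adipogenic genes 3 were higher, among them FABP5 (2.46) and PPARG (1.56), 4 were lower and 23 did not pass, with the same counts over the list alone (adjusted p = 0.750). Of 39 neural genes 7 were higher, among them NES (2.73), 5 were lower, among them ENO2 (-1.87), and 27 did not pass, with the same counts over the list alone (adjusted p = 0.815).

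Of 36 stromal surface markers 10 were higher, 10 lower and 16 did not pass (11 and 11 adjusted over the list alone; adjusted p = 0.750), with F3, tissue factor (2.56), and ICAM1 (2.28) higher and MCAM, a marker of perivascular cells, lower (-2.50). Of 59 matrix genes 13 were higher, 19 lower and 27 did not pass (15 and 21 adjusted over the list alone; adjusted p = 0.0972, 0.00421 with dim genes left out and just under the threshold over both array types, both as lower, with a range of 0.00421 to 0.162 over its alternatives), with COL4A5 higher (2.99) and COL8A1 (-3.83) and the protease inhibitor TIMP3 (-3.29) lower. Of 26 imprinted and fetal growth genes 6 were higher, 3 lower and 17 did not pass, with the same counts over the list alone (adjusted p = 0.184). IGF2BP3, a fetal RNA-binding protein (4.04), and HMGA2 were higher, and MEST was lower (-3.53). Of 17 pluripotency genes 2 were higher, 2 lower and 13 did not pass (3 and 2 adjusted over the list alone; adjusted p = 0.750).

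The haematopoietic, endothelial and epithelial lists were called lower in UCB1 than in BM by the set test with the preset correlation. Most of their genes did not pass, and the list calls were lost with an estimated correlation. Of 34 haematopoietic genes 0 were higher, 3 lower, among them SRGN and the leukocyte integrin ITGB2 (-1.10, both means within the range of the unspiked controls), and 31 did not pass, with the same counts over the list alone (set test adjusted p = 0.0320, 0.0135 to 0.128 over the other alternatives, and adjusted p = 0.413 with an estimated correlation). The value was 0.0546 without UCB1 replicate 2 and 0.0650 without BM replicate 2. Of 27 endothelial genes 1 was higher, 6 lower, among them ICAM2 (-1.47), and 20 did not pass, with the same counts over the list alone (set test adjusted p = 0.0411, 0.0311 to 0.0907 over the other alternatives, and adjusted p = 0.300 with an estimated correlation). The value was 0.0642 without UCB1 replicate 2 and 0.0709 without BM replicate 2. The 6 lower were 3 without UCB1 replicate 2, without UCB1 replicate 3 or without BM replicate 2. Of 27 epithelial genes 2 were higher, among them CLDN11 (1.65), 7 lower, among them the keratins KRT7 (-4.03) and KRT14 (-3.17), and 18 did not pass, with the same counts over the list alone (set test adjusted p = 0.0289, 0.0115 to 0.0892 over the other alternatives, and adjusted p = 0.236 with an estimated correlation). The adjusted p of the haematopoietic, endothelial and epithelial lists was 0.0891, 0.0907 and 0.0535 with quantile normalization, 0.128, 0.0577 and 0.0892 without dim genes, and 0.0728, 0.0791 and 0.0574 without the 2 cultures that stood apart. Median, mean and set test of a list differed in sign in this comparison for other patterning factors, WNT, Notch, FGF, adipogenic, neural, pluripotency, inflammatory and sterol synthesis genes.

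Over HG-U133A 5729 probe sets differed between UCB1 and BM, 3284 higher and 2445 lower in UCB1, and 1316 of them differed at least 2-fold. Over HG-U133B 399 differed, 45 higher and 354 lower. When only UCB1 and BM arrays were fitted 191 differed. On HG-U133B 1393 differed without UCB1 replicate 2, 578 higher and 815 lower. Higher and lower counts were 20 and 196 without UCB1 replicate 1, 142 and 447 without UCB1 replicate 3, 28 and 250 without UCB2 replicate 1, 36 and 311 without UCB2 replicate 2, and 30 and 244 without UCB2 replicate 3. Without BM replicates 1, 2 and 3 they were 9 and 165, 13 and 164, and 12 and 182. Of list members called lower in UCB1, HG-U133A held 13 of 14 other patterning, 17 of 18 TGF-beta and BMP and 3 of 4 adipogenic genes. It also held 10 of 11 smooth muscle, 9 of 10 stromal surface and 19 of 20 hypoxia genes, and the rest were read on HG-U133B. The set test called 11 lists in this comparison, 7 without UCB1 replicate 2, 5 with quantile normalization and 0 with an estimated correlation. The lower group also lay within the range of the unspiked controls, which limits the fold, for 24 genes named from lists: HOXD11, HOXB7, TBX3, MEIS1, IRX3, WNT2, SFRP4, BAMBI, FGF13, FGF7, DLGAP5, NEK2, DLX5, PPARG, COMP, F3, COL4A5, COL8A1, IGF2BP3, ITGB2, ICAM2, KRT7, KRT14 and BST2.

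Cord blood population UCB2 was compared with the same marrow cultures. MMP1 was 157-fold higher in UCB2 than in BM (10.05 ± 0.37 against 2.75 ± 0.06, SD, n = 3 each), CCND2 60.6-fold (10.03 ± 0.78 against 4.11 ± 0.11) and IL1B 25.6-fold (10.43 ± 0.35 against 5.76 ± 0.14). BM had 107-fold more FLG (2.73 ± 0.09 in UCB2 against 9.48 ± 0.05), 94.9-fold more CXCL12 (3.12 ± 0.30 against 9.69 ± 0.17) and 69.4-fold more SULF1 (4.04 ± 0.61 against 10.16 ± 0.05). The adjusted p values were 4.68e-08 for MMP1, 7.21e-07 for CCND2, 2.43e-08 for IL1B, 4.18e-11 for FLG, 1.53e-07 for CXCL12 and 2.3e-07 for SULF1 (limma).

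Other genes with the largest differences toward UCB2 were GREM1 (4.61), COL4A5, a basement membrane collagen (4.57), DNER (4.50), NEFM (4.05), CDCP1, a surface protein (3.99), SCG5, a secretory granule chaperone (3.91), and HMGA2 (3.91). Toward BM these were DCN (-6.05), TNFRSF11B (-5.62), MFAP5 (-5.31), FNDC1 (-4.92), ISLR (-4.91), LIMCH1 (-4.88) and PLPP3, a lipid phosphatase (-4.85). Adjusted p values of these genes ranged up to 2.76e-04, the value of DNER. In 16 of these 20 genes the mean of the lower group lay within the range of the unspiked controls. This limits their folds, and MMP1, CCND2, FLG, CXCL12 and SULF1 were among them.

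Of 27 HOX genes 0 were higher in UCB2 than in BM, 8 lower and 19 did not pass (0 and 12 adjusted over the list alone; set test adjusted p = 3.45e-05, 4.26e-07 to 2.42e-04 over the other alternatives, and adjusted p = 0.173 with an estimated correlation). HOXC6 (-3.57 ± 0.14, SE), HOXC10 (-3.33 ± 0.22) and HOXB7 (-2.02 ± 0.15) were lower. Of 81 other patterning factors 8 were higher, 13 lower and 60 did not pass (9 and 14 adjusted over the list alone; set test adjusted p = 0.0690), with ZIC1 higher (2.96) and the homeobox factor EMX2 lower (-3.00). Of 53 WNT genes 3 were higher, 8 lower and 42 did not pass (3 and 9 adjusted over the list alone; adjusted p = 0.0690, and 0.0331 as lower with dim genes left out, range 0.0331 to 0.0991 over its alternatives), with FZD2 higher (1.45) and SFRP4 lower (-2.39). Of 38 Notch genes 3 were higher, among them ADAM17 (0.92), 2 lower and 33 did not pass (4 and 2 adjusted over the list alone; adjusted p = 0.691). Without UCB1 replicate 2 and UCB2 replicate 2 together, 6 Notch genes were higher and 4 lower. Of 59 TGF-beta and BMP genes 8 were higher, 16 lower and 35 did not pass (10 and 17 adjusted over the list alone; adjusted p = 0.138), with TGFB2 (2.64) and the receptor TGFBR2 (1.88) higher and the BMP target ID3 lower (-2.03). Of 35 FGF genes 4 were higher, among them the inhibitor SPRY2 (1.52), 2 lower, among them the receptor FGFR2 (-3.41), and 29 did not pass, with the same counts over the list alone (adjusted p = 0.958). Of 15 hedgehog genes 1, HHIP, was higher (1.99), 2 were lower and 12 did not pass, with the same counts over the list alone (adjusted p = 0.0544). The hedgehog list passed as lower without UCB2 replicate 2 (adjusted p = 0.0319), without the 2 cultures that stood apart (0.0381) or without BM replicate 1 (0.0411), with a range of 0.0319 to 0.295 over its alternatives. These set tests used the 9 hedgehog genes on HG-U133A, without HHIP, which was read on HG-U133B. Over both array types, with HHIP included, the adjusted p of the set test was 0.295.

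Of 55 proliferation genes 1 was higher in UCB2 than in BM, 5 lower, among them the thymidine kinase gene TK1 (-1.04), and 49 did not pass (0 and 1 adjusted over the list alone, median log2 difference -0.35; set test adjusted p = 0.00587, 1.27e-16 to 0.108 over the other alternatives, and adjusted p = 0.695 with an estimated correlation). This adjusted p was 0.108 without UCB2 replicate 1 and 0.0953 without UCB2 replicate 3. Without UCB2 replicate 2, 37 genes of the list were lower and 0 higher. The lower count was 1 without UCB2 replicate 1, UCB2 replicate 3 or any 1 of the BM cultures, and 3 without UCB1 replicate 3. Of 31 growth arrest genes 6 were higher, 11 lower and 14 did not pass (6 and 13 adjusted over the list alone; adjusted p = 0.0550), and this list passed as lower without UCB2 replicate 1 (0.0458), over both array types (0.0126) or with dim genes left out (0.0148), with a range of 0.0126 to 0.146 over its alternatives. CDKN2A was 4.69-fold higher in UCB2, and 7.61-fold without UCB2 replicate 2, and IGFBP3 was lower (-3.44).

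Of 34 hypoxia and glycolysis genes 5 were higher in UCB2, among them P4HA2, a collagen hydroxylase (0.72), 10 lower, among them MXI1, an antagonist of MYC (-0.98), and 19 did not pass (5 and 12 adjusted over the list alone; set test adjusted p = 0.0384, 0.00766 to 0.134 over the other alternatives, and adjusted p = 0.459 with an estimated correlation). The value was 0.111 without UCB2 replicate 2, 0.134 without the 2 cultures that stood apart and 0.0609 with quantile normalization. The 5 higher became 1 without BM replicate 1, BM replicate 2, UCB2 replicate 1 or UCB2 replicate 3, 2 without BM replicate 3 and 3 without UCB1 replicate 3. Of 37 interferon and antigen presentation genes 6 were higher, among them HLA-B (0.91), 7 lower, among them GBP2 (-1.16), and 24 did not pass (7 and 8 adjusted over the list alone; adjusted p = 0.328). Of 38 inflammatory and support factors 10 were higher, 6 lower and 22 did not pass (12 and 7 adjusted over the list alone; adjusted p = 0.691). LIF, a cytokine of the IL6 family (1.96), and CCL20 (2.09) were higher, and PTGES was lower (-2.70). The 10 higher were 6 without BM replicate 1 or BM replicate 2, and the 6 lower were 10 without UCB2 replicate 2. Of 19 sterol synthesis genes 2 were higher, among them NSDHL (0.82), 0 lower and 17 did not pass, with the same counts over the list alone (adjusted p = 0.189), and this list passed as higher without UCB2 replicate 2 (0.0318) or without the 2 cultures that stood apart (0.0321), with a range of 0.0318 to 0.779 over its alternatives.

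Of 59 matrix genes 5 were higher in UCB2 than in BM, 25 lower and 29 did not pass (7 and 29 adjusted over the list alone, median log2 difference -0.42; set test adjusted p = 1.26e-06, 3.02e-08 to 1.97e-05 over the other alternatives, and adjusted p = 0.0644 with an estimated correlation). FBLN1 (-4.09) and LUM (-4.02) were lower beside DCN, and COL13A1 was higher (3.42). Of 27 chondrogenic genes 2 were higher, among them SOX9 (1.58), 5 lower, among them COMP (-4.34), and 20 did not pass (2 and 9 adjusted over the list alone; set test adjusted p = 0.00617, 0.00159 to 0.0211 over the other alternatives, and adjusted p = 0.173 with an estimated correlation). Of 29 smooth muscle genes 3 were higher, among them ACTG2 (1.15), 10 lower, among them ACTA2 (-4.29) and SYNPO2 (-4.13), and 16 did not pass (4 and 10 adjusted over the list alone; set test adjusted p = 0.00931, 0.00159 to 0.0239 over the other alternatives, and adjusted p = 0.199 with an estimated correlation). Of 26 imprinted and fetal growth genes 11 were higher, among them IGF2BP3 (3.59) and HMGA2, 3 lower and 12 did not pass (13 and 4 adjusted over the list alone; set test adjusted p = 0.0245, 0.00915 to 0.0320 over the other alternatives, and adjusted p = 0.173 with an estimated correlation), and the 11 higher were 7 without BM replicate 1 or BM replicate 2.

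Of 25 osteogenic genes 2 were higher in UCB2, 5 lower, among them DLX5 (-1.05), and 18 did not pass (2 and 7 adjusted over the list alone; adjusted p = 0.111, and 0.0118 as lower with dim genes left out, range 0.0118 to 0.201 over its alternatives). Of 30 adipogenic genes 1, FABP5, was higher (2.28), 6 lower, among them CEBPD (-2.35), and 23 did not pass (1 and 7 adjusted over the list alone; adjusted p = 0.0550). The 6 lower were 3 without BM replicate 2, and the list passed as lower without BM replicate 1 (0.0185) or over both array types (0.0213), with a range of 0.0185 to 0.184 over its alternatives. Of 39 neural genes 5 were higher, among them NEFM and SYT1 (1.30), 2 lower, among them STMN2 (-0.59, both means within the range of the unspiked controls), and 32 did not pass, with the same counts over the list alone (adjusted p = 0.917). The 5 higher were 3 without any 1 of the BM cultures, without UCB2 replicate 1 or without UCB2 replicate 3. Of 36 stromal surface markers 8 were higher, among them ICAM1 (3.71), 10 lower, among them PDGFRA (-3.39) and THY1 (-2.41), and 18 did not pass (9 and 11 adjusted over the list alone; adjusted p = 0.111). Of 17 pluripotency genes 1, MYC, was higher (0.95), 1 lower and 15 did not pass, with the same counts over the list alone (adjusted p = 0.778).

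Markers of other cell types did not pass the set test in UCB2 against BM. Of 34 haematopoietic genes 0 were higher, 4 lower, among them ITGB2 (-0.86, both means within the range of the unspiked controls), and 30 did not pass (0 and 2 adjusted over the list alone; adjusted p = 0.0690). This list passed as lower without UCB2 replicate 2 (0.0319), without BM replicate 1 (0.0447), over both array types (0.0389) or without the 2 cultures that stood apart (0.0307), with a range of 0.0307 to 0.310 over its alternatives. Of 27 endothelial genes 0 were higher, 2 lower, among them ICAM2 (-1.36), and 25 did not pass, with the same counts over the list alone (adjusted p = 0.240). Of 27 epithelial genes 3 were higher, among them CLDN1 (2.18), 5 lower, among them KRT14 (-2.98), and 19 did not pass (4 and 7 adjusted over the list alone; adjusted p = 0.0690, and 0.0314 as lower over both array types, range 0.0314 to 0.184 over its alternatives). Median, mean and set test of a list differed in sign in this comparison for Notch, FGF and pluripotency genes, and the median of the TGF-beta and BMP list was 0.00.

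Over HG-U133A 4432 probe sets differed between UCB2 and BM, 2539 higher and 1893 lower in UCB2, and 967 of them differed at least 2-fold. The count was 2915 without BM replicate 2, 1608 of them higher, and 2935 without BM replicate 3, 1629 of them higher. Over HG-U133B 211 differed, 56 higher and 155 lower. When only UCB2 and BM arrays were fitted 1223 differed. On HG-U133B 1262 differed without UCB1 replicate 2, 531 higher and 731 lower. Higher and lower counts were 44 and 134 without UCB1 replicate 1, 43 and 141 without UCB1 replicate 3, 35 and 104 without UCB2 replicate 1, 88 and 110 without UCB2 replicate 2, and 28 and 90 without UCB2 replicate 3. Without BM replicates 1, 2 and 3 they were 25 and 100, 21 and 92, and 28 and 118. The lower group also lay within the range of the unspiked controls, which limits the fold, for 22 genes named from lists: HOXC6, HOXC10, HOXB7, ZIC1, EMX2, SFRP4, FGFR2, HHIP, TK1, DLX5, COMP, SYT1, STMN2, COL13A1, FBLN1, IGF2BP3, ITGB2, ICAM2, CLDN1, GBP2, CCL20 and KRT14.

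The cord blood populations shared differences from marrow cells. MMP1, GREM1, HMGA2 and IGF2BP3 were higher in both, and FLG, MFAP5, ISLR, COMP and FNDC1 were lower in both. On HG-U133A 2708 probe sets differed from BM in the same direction in UCB1 and UCB2, 1468 higher and 1240 lower in both, and 180 differed in opposite directions. Independent lists of these sizes would share 584. Unchanged groups simulated 20 times against the same BM cultures shared 0, a count near 0 by construction that says nothing of the shared controls. The covariance of the log2 differences was 0.176 against 0.0121 simulated, and their correlation 0.566 against 0.502. The BM cultures are too few to be split between the comparisons, so part of the excess may come from the shared controls. The 2708 were 1732 without BM replicate 2 and 1803 without BM replicate 3. On HG-U133B 134 probe sets went the same way, with 2.54 from independent lists, a covariance of 0.0590 against 0.0327 simulated and a correlation of 0.430 against 0.496, and 6 went opposite ways. The 134 were 609 without UCB1 replicate 2, 88 without UCB2 replicate 3 and 82 without BM replicate 2.

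**Figure D4:**
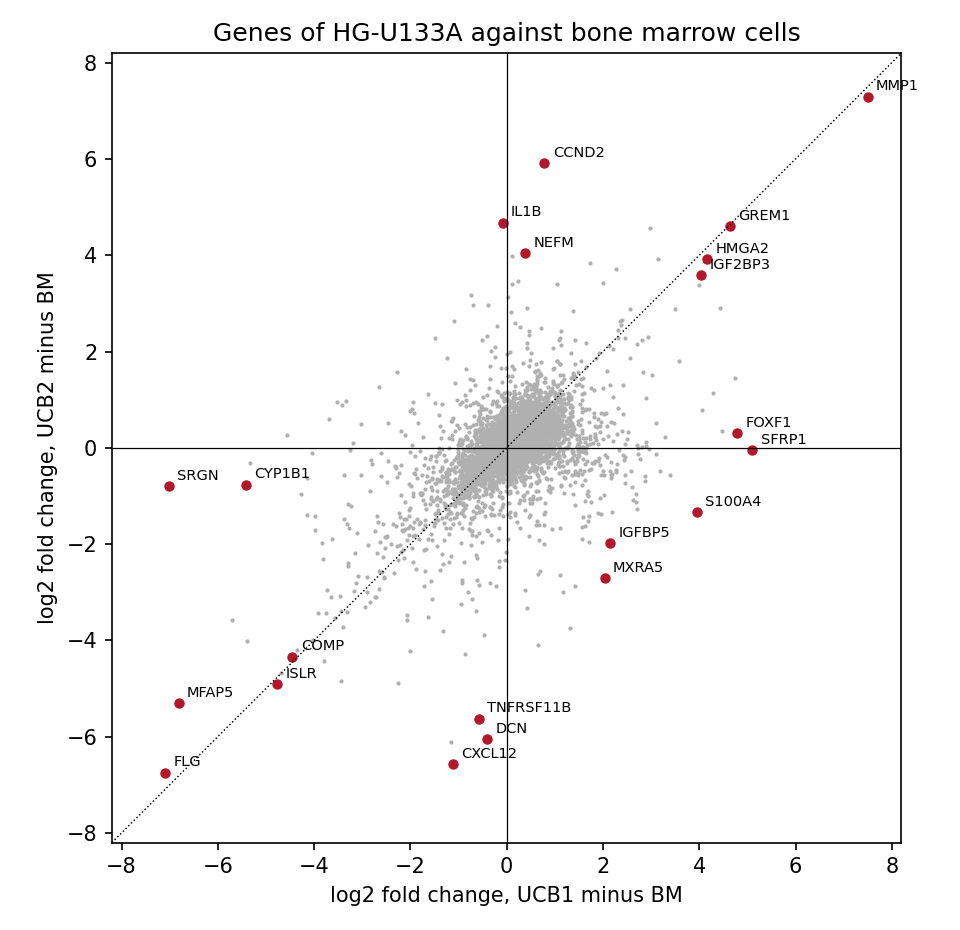
Log2 difference from BM of UCB1 (horizontal) and UCB2 (vertical) for the 11783 genes of HG-U133A, 1 grey point per gene, with named genes in red and equal differences on the dotted line. MMP1 and FLG lie near the dotted line at its ends, SRGN, CYP1B1 and SFRP1 lie near the horizontal axis, and CXCL12, DCN and CCND2 near the vertical axis.

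Any difference among the 3 groups was found for 6806 probe sets of HG-U133A and 392 of HG-U133B by the F test (limma). On HG-U133B the count was 1864 without UCB1 replicate 2, 242 without UCB1 replicate 1, 246 without UCB2 replicate 1, 241 without UCB2 replicate 3, and 201, 180 and 210 without BM replicates 1, 2 and 3. With an estimated correlation the set test called 0 of 25 lists in each comparison, and the unadjusted p was under 0.05 for 2 lists in UCB1 against UCB2, 3 in UCB1 against BM and 7 in UCB2 against BM.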

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

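Every test in this part was chosen after the result it measures was seen. An array was singled out where its gap to the nearest of the other 8 was large against the whole range (Dixon's test). The lowest and the highest of each 9 values were tested separately, which gave 32 tests. Chance singles out about 1 in 20 groups of 9 values over both ends together, so fewer of the single tests. That rate holds for values of 1 normal sample, while these arrays come from 3 groups. Here 9 of 32 tests singled out an array, 5 of them the same array.

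The HG-U133B array of UCB1 replicate 2 lay far from the others in its median (4.97), its SD over probe sets (0.871), its mean correlation with the other arrays (0.662), its spiked controls (6.54) and its unspiked controls (4.46). A fault of the culture or of its RNA before division between the arrays is argued against by the HG-U133A array of that culture. Its lowest correlation with its own group was 0.988, inside the range of 0.984 to 0.996 of same-group pairs of the other arrays. A sample of another group under a wrong label is argued against as well, because on 2136 probe sets called without this array its values correlated with the pattern of UCB1 at 0.258, against -0.0285 for UCB2 and -0.235 for BM, and UCB1 was highest in 10 of 10 parts of these probe sets. Weak hybridisation of that array remains a candidate explanation, since the spiked controls, which are independent of the cells, read 6.54 against 8.52 to 8.87. No biological explanation was tested.

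The proliferation genes of UCB2 replicate 2 lay above those of the other UCB2 cultures in 55 of 55 genes. Genes that vary separately would give 18.3, but genes of this list move together (estimated correlation 0.716). A shift of 1 culture therefore moves most of them at once, and the 55 are not separate observations. UCB1 cells mixed into that culture are argued against, because 42 genes outside the list that were at least 8-fold higher in UCB1 moved toward UCB1 by a median share of 0.00481 on the linear scale, against 0.264 in 19 proliferation genes. Array or RNA quality is argued against too, with a GAPDH 3-prime minus 5-prime difference of -0.187 and spiked controls of 8.67, both inside the range of the other arrays. A difference in growth between the UCB2 cultures may remain, and it was not tested. The same array had the highest mean correlation with the other HG-U133A arrays, 0.969.

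The 18S rRNA control of BM replicate 1 read 8.95 on HG-U133A and 9.21 on HG-U133B, far above the other arrays. The ACTB 3-prime minus 5-prime difference of UCB2 replicate 3 on HG-U133A was -0.31, far above the next of -0.60.

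UCB1 and UCB2 lay on opposite sides of BM, each past the threshold, in 180 probe sets of HG-U133A and 6 of HG-U133B. Their own difference is the sum of the 2 and follows from this selection.

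The arrays were also regrouped. For UCB1 against UCB2 the real grouping gave 3053 calls on HG-U133A and 121 on HG-U133B, for UCB1 against BM 5729 and 399, and for UCB2 against BM 4432 and 211. The highest of the other splits gave 0 in each case, and 1 of 10 splits, the real one, was as large. With 10 splits the share cannot fall under 0.1. For any difference among 3 groups 1 of 100 splits, the real one, reached 6806 calls on HG-U133A and 392 on HG-U133B, and the highest others gave 2015 and 113, so chance is excluded for these 2 counts at a share of 0.05.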

How the results depend on the processing

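Array weights, and the fits without UCB1 replicate 2 and UCB2 replicate 2 together, were chosen after seeing the data. Of the 454 gene and comparison pairs of the naming rule, 392 kept their call on the same probe set in every alternative and 62 lost it in at least 1, 55 of them when 1 culture was left out, and 0 turned direction on that probe set. Of 288 pairs with other probe sets, 73 had at least 1 of opposite sign. In 1 of these, EBP for UCB1 against BM, such a probe set was called. The 218 pairs named in the text were picked partly for calls that held, so their stability says nothing about other genes. Of those, 216 passed with only the 2 groups compared. Their other probe sets gave 171 calls in the same direction, 88 without a call in the same direction and 13 of opposite sign, none of the 13 called. The latter were, for UCB1 against UCB2, DCN -0.051, ZIC1 0.282 and 0.055, NEFM 0.138, ACTA2 -0.128, ACTG2 -0.15 and PDGFRA -0.079. For UCB1 against BM they were ACTG2 -0.243 and ANKRD37 0.147, and for UCB2 against BM DCN 0.021, LIMCH1 0.082, ACTG2 -0.093 and PDGFRA 0.034. Among the 88 were small values for genes named with large differences. For UCB1 against BM these included SYNPO2 -0.051, KRT7 -0.008 and COL8A1 -0.019. For UCB2 against BM they included SYNPO2 -0.369 and FGFR2 from -0.021 to -0.182. The cause was not tested.

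Counts in this paragraph follow the order UCB1 against UCB2, UCB1 against BM, UCB2 against BM and any difference. With 1 probe set per gene, which tests fewer probe sets, HG-U133A gave 1962, 3513, 2729 and 4165 calls and HG-U133B 42, 114, 63 and 125. A 2-fold limit left 1019, 1316 and 967 on HG-U133A, and on HG-U133B 234 for UCB1 against BM and 127 for UCB2 against BM. A threshold of 0.01 left 4095 and 183 for any difference. On HG-U133B, fitting only the groups compared gave 19, 191 and 1223, and joint adjustment with HG-U133A gave 378, 912, 522 and 955. Array weights, estimated gene by gene because the REML method did not converge, gave 914, 1578, 2066 and 2558 on HG-U133B, with a weight of 0.0353 for UCB1 replicate 2, and fits without the 2 cultures that stood apart 1412, 1755, 1527 and 2430.

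Leaving out 1 culture gave ranges of 2216 to 3568, 4015 to 6175, 2915 to 4818 and 4987 to 7444 on HG-U133A, and of 60 to 812, 174 to 1393, 113 to 1262 and 180 to 1864 on HG-U133B. All 4 highest values on HG-U133B came without UCB1 replicate 2. Where a culture left a group with 2, the spread came from all groups. Probe sets that differed from BM the same way in UCB1 and UCB2 numbered 1732 to 2657 on HG-U133A and 82 to 609 on HG-U133B. They were 464 and 75 with the 2-fold limit, 84 on HG-U133B without dim probe sets and 640 there without the 2 cultures that stood apart.

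With the replicate number as a block, HG-U133B gave 66 calls for UCB1 against UCB2, 6 higher and 60 lower. There it gave 21 higher instead of 45 for UCB1 against BM, and 66 instead of 183 for any difference at a threshold of 0.01, and the other totals of calls stayed within 1.5 times. By the set test it changed 2 calls, the interferon list in UCB1 against BM (adjusted p = 0.0514, range 0.00370 to 0.0936) and the hedgehog list in UCB2 against BM (0.0396, range 0.0319 to 0.295), and no call of a gene named in the text. Residuals of equal replicate numbers in different groups correlated at r from -0.26 to 0.20 on HG-U133A and from -0.09 to 0.30 on HG-U133B, and 3 of 9 pairs on each were the best match. UCB1 and UCB2 pairs gave 0.236, 0.304 and 0.182 on HG-U133B, all above 0.1, but 0.156, -0.265 and 0.0940 on HG-U133A, so pairing stays open for that comparison on HG-U133B, and the other pairs were not all above 0.1.

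The set test with an estimated correlation called 0 lists in each comparison. The counts that follow are of the set test with the preset correlation. For UCB1 against BM it called 5 with quantile normalization and 5 without the 2 cultures that stood apart, and 7 to 11 without 1 culture. For UCB2 against BM it called 11 over both array types, and 6 to 10 without 1 culture, and for UCB1 against UCB2 3 to 4 without 1 culture. Without dim genes 23 of the lists could be tested. The lower group lay within the range of the unspiked controls, which limits the fold, in 64 of 140, 77 of 161 and 75 of 153 genes of the naming rule, in the order of comparisons above. The 100 probe sets present on both array types gave log2 differences that correlated at r = 0.59 for UCB1 against UCB2, and 0.87 without UCB1 replicate 2. Between the array types these log2 differences were apart by a median of 1.15 for UCB1 against UCB2 and 1.09 for UCB1 against BM. Without UCB1 replicate 2 the medians were 0.116 and 0.0264. For UCB2 against BM the median was -0.0897. The array of UCB1 replicate 2 thus shifted log2 differences of UCB1 on HG-U133B in these probe sets.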

Other observations

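The tests in the last paragraph of this part, and the genes named here, were chosen after the values were seen.

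UCB1 and UCB2 lay on opposite sides of BM in 119 genes with 1 probe set each. Of these, 66 were higher in UCB1 and lower in UCB2 and 53 the reverse, and 4 belonged to the proliferation list. Among the largest differences on both sides were IGFBP5 (2.14 and -1.98), MXRA5 (2.03 and -2.71), BEX1 (-2.28 and 1.56) and NXN (1.43 and -2.87). The UCB2 mean of MXRA5 lay within the range of the unspiked controls.

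A hypothesis was that the difference in proliferation between the populations accounts for other differences between UCB1 and UCB2. In UCB2 replicate 2 the proliferation genes lay between those of UCB1 and of the other UCB2 cultures, at a median share of 0.537 of the way on the log2 scale (quartiles 0.431 and 0.620, 51 genes). Of genes called without that culture, the median share was 0.306 in 2122 outside the list (quartiles 0.0502 and 0.607) and 0.0715 in the 74 of these that differed at least 8-fold (upper quartile 0.296). It was 0.223 in 25 hypoxia and glycolysis genes (upper quartile 0.360), 0.129 in 34 matrix genes (0.286) and 0.00550 in 7 HOX genes (0.145). Calling genes from the other UCB2 cultures can by itself put the shares of UCB2 replicate 2 above 0, most where differences are small. All these shares rest on 1 culture, which excludes nothing. For the called genes outside the list, the hypoxia list included, population and growth therefore cannot be told apart.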
